A study of Rattus norvegicus with 32 samples.

How the data were processed

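RNA of gastrocnemius muscle from male control and UCP1 knockout rats was sequenced from the 3′ end of transcripts (QuantSeq libraries from 500 ng of Trizol-prepared RNA, 50 bp forward reads). Per the labels, the 32 libraries fall into 4 groups: 7 of control rats at room temperature (control_RT), 7 of control rats after 2 weeks at 4 °C (control_4C), 9 of knockout rats at room temperature (KO_RT) and 9 of knockout rats at 4 °C (KO_4C). The rats were 20 weeks old and, per the series title, chow-fed. The labels do not say whether room-temperature and cold samples came from separate animals. The columns of the KO_RT libraries are numbered as in the sample titles, while the descriptions number the same samples differently, so these libraries are named by their column (KO8, KO10 and so on).

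The authors deposited a table of raw counts, whole-number counts of reads per Ensembl gene, and a table of normalised signal, in which each deposited count was divided by 1 size factor per library (0.523 to 2.06). Per the labels, the processing used R 3.4.3, DESeq2 1.18.1 and the genome build Rnor_6.0; the aligner and the counting tool are not given in the sources used here. The table held 12901 genes, and the smallest sum of counts of a gene over the libraries was 96. No odd count occurred, so each read appears to have entered the table in duplicate; totals and CPM are given as deposited, and counts divided by 2 were one of the alternatives. Library totals ran from 7.28e+06 to 2.58e+07 counts. At this depth counting error was small for the abundant muscle genes and mattered for genes of a few CPM. No pair of libraries of a group was a duplicate of another (smallest chi-square per degree of freedom 6.19).

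Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. After filterByExpr (minimum count 10, smallest group 7), 11594 genes were tested and 1307 were not. TMM factors, 1 mean per group and no covariate entered a robust quasi-likelihood fit over all 32 libraries, and contrasts were tested with the quasi-likelihood F test, adjusted per contrast by the Benjamini-Hochberg method at 0.05. Each fold change is given with a standard error (SE), computed as its absolute log2 value over the square root of the F statistic. CPM values carry the SD between libraries. The p-values measure the spread between samples. The contrasts were cold in control rats, cold in knockout rats, knockout against control at room temperature, the same at 4 °C, and the interaction, which is the cold response of knockout rats minus that of control rats.

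Before the data were examined, 32 gene lists were fixed: muscle programs (calcium cycling, slow oxidative fibre, fast glycolytic fibre, satellite cell and denervation, atrophy and autophagy), metabolism (nuclear-encoded oxidative phosphorylation, mitochondrial DNA-encoded, citric acid cycle, fatty acid oxidation, PPAR and fasting, glycolysis, lipid synthesis, creatine cycle), cell types (brown adipocyte, adipocyte, endothelial, smooth muscle, fibroblast and matrix, tendon, macrophage, Schwann cell, erythroid), regulators (mitochondrial biogenesis, glucocorticoid, thyroid hormone, circadian clock, immediate-early, heat shock, unfolded protein, interferon, oxidative stress) and ribosomal proteins. Lists were tested with camera on log2 CPM (prior count 2, inter-gene correlation preset at 0.01), adjusted over the 32 lists of a contrast. Beside it stood camera with an estimated correlation and fry, which asks whether the genes of a list move, on balance, one way without comparing them with other genes. A list of 31 intestinal epithelial markers, 26 of them tested, was written after the data were seen.

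Named genes followed a rule fixed before the data were examined. Per pairwise contrast these were the 6 genes of largest fold change and the 4 of smallest p in each direction, with an adjusted p under 0.05, a mean of at least 5 CPM and a symbol that is no placeholder. From each list the 3 members of smallest p past the threshold were added. For the interaction the rule took the 8 genes of smallest p past the threshold. Ucp1, Sln, Pln, Atp2a1, Atp2a2, Ryr1, Ucp2, Ucp3, Ppargc1a, Pdk4, Myh7, Myh2, Myh1 and Myh4 were to be looked up always; the text gives a selection of the genes so named. Symbols came from the deposited table (11693 genes) and from the Entrez IDs of the reference table (11138 matches). Gene positions and chromosomes were used only for the test of genes near Ucp1, which compares windows in gene order and the chromosome of Ucp1 with the rest. Transcript features were not used here.

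Alternatives fixed before the data were examined were RLE factors, factors without the 20 most abundant genes, no filter, DESeq2 1.42.0, 1 surrogate variable (sva 3.50.0), the slow-fibre list as a covariate, a fit of the compared groups alone, replicate numbers as a block, an adjusted p of 0.01, a minimum of 10 CPM for the similarity of the cold responses, and leaving out each library in turn. Chosen after seeing the data were counts divided by 2, 3 sets of libraries left out, and 2 further covariates. The first covariate was the intestinal list. The other was a transcript-loss index: the mean log2 CPM of the 94 genes, 2% of those with a mean log2 CPM above 4, that were lowest in column KO10 relative to the other KO_RT libraries apart from KO8. In data with simulated changes in 1.5-, 2- and 4-fold steps, the fit recovered 37.3%, 61.2% and 83.3% for cold in control rats and 14.9%, 46.3% and 84.8% for the interaction, and wrong calls were 1.48% to 5.37% of calls over the 5 contrasts. The simulation drew each gene independently, without differences shared by many genes of a library, so these rates need not hold for the real libraries. There, other splits of the samples gave up to 810 genes for cold in control rats and 765 for knockout at room temperature. Every per-sample column of the table was used.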

Results

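The series measured gene expression in the gastrocnemius, a calf muscle made mainly of fast fibres, in control rats and in rats lacking UCP1, the proton channel with which brown fat makes heat. Each genotype was sampled at room temperature and after 2 weeks at 4 °C, with 7 libraries per control group and 9 per knockout group. The comparisons ask how muscle responds to prolonged cold, and whether it differs when UCP1 is missing. Library totals averaged 1.42e+07 ± 2.38e+06 counts in control_RT (SD, n = 7), 1.31e+07 ± 4.62e+06 in control_4C (n = 7), 1.37e+07 ± 2.67e+06 in KO_RT (n = 9) and 1.36e+07 ± 5.93e+06 in KO_4C (n = 9). Ucp1 itself was not analysed here, so the genotype labels were not checked by it, and Atp2a1, Myh2 and Myh4 were not analysed here either.

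The libraries differed in several measures beside the groups. The first principal component held 21.7% of the variance. A transcript-loss index, defined after the data were seen as the mean log2 CPM of 94 genes low in column KO10, was 4.71 ± 0.57 in control_RT (SD, n = 7), 5.92 ± 0.14 in control_4C (n = 7), 5.50 ± 0.90 in KO_RT (n = 9) and 5.96 ± 0.17 in KO_4C (n = 9). It lay lower in control_RT than in control_4C (two-sided exact permutation p = 0.000583). Within KO_RT the columns KO8 and KO10 stood at 4.23 and 3.70. KO10 is low by construction, as the genes were chosen for it, which lowers the KO_RT mean. These columns and control_RT replicates 2 and 3, lowest on the first component, were also the lowest on the index. Intestinal epithelial transcripts made up 0.0931% ± 0.0422 of counts in control_RT, 0.120% ± 0.0774 in control_4C, 0.0674% ± 0.0184 in KO_RT and 0.0566% ± 0.010 in KO_4C. Their share was highest in control_4C replicates 3 (0.258%) and 6 (0.200%) and in control_RT replicate 4 (0.180%). Mitochondrial transcripts took 11% ± 0.56 of counts in control_RT, 8.6% ± 1.0 in control_4C, 11% ± 1.2 in KO_RT and 9.8% ± 1.3 in KO_4C. The 10 most abundant genes of each library took 29.4% ± 1.42 in control_RT, 24.5% ± 0.769 in control_4C, 27.8% ± 1.15 in KO_RT and 24.3% ± 0.848 in KO_4C. This share did not overlap between temperatures in either genotype.

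**Figure D1:**
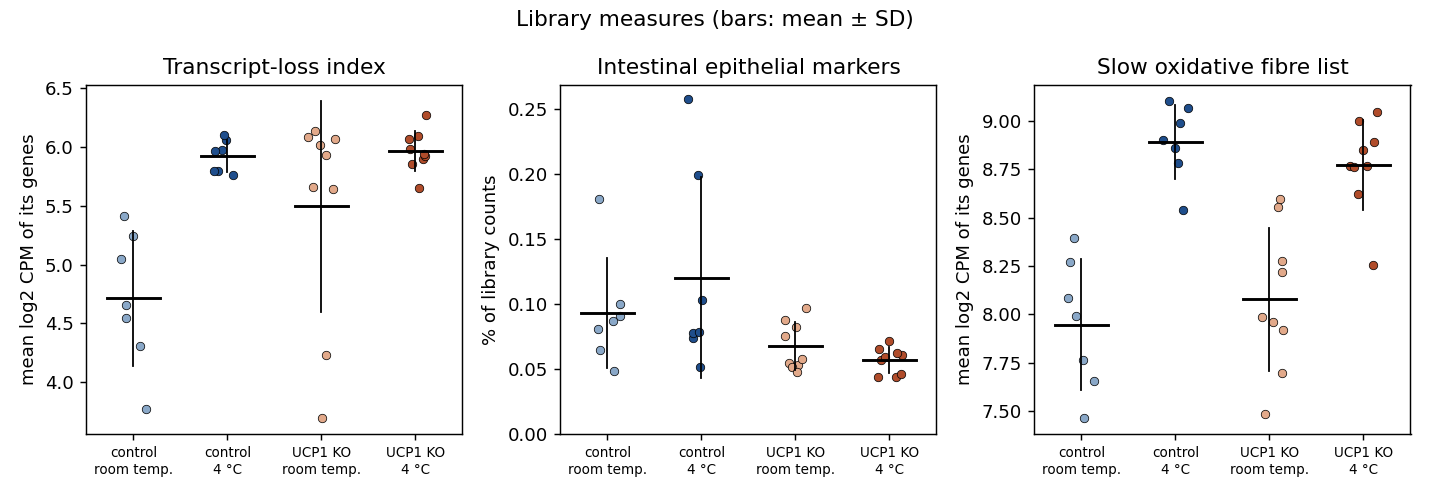
Library measures by group: the transcript-loss index (mean log2 CPM of its genes), the share of counts of intestinal markers (%) and the mean log2 CPM of the slow oxidative fibre list; points are libraries, and bars give the mean ± SD. The slow-fibre mean was 7.95 in control_RT and 8.89 in control_4C, and the 2 lowest KO_RT points of the loss index are columns KO8 and KO10.

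In control rats, camera called the slow-fibre and fat oxidation lists higher and the glycolysis list lower in muscle after 2 weeks of cold. None of these calls held with an estimated correlation (adjusted p = 0.225, 0.282 and 0.258), and the transcript-loss index separated the groups without overlap. Sarcolipin (Sln, ENSRNOG00000009047), a small peptide that uncouples the calcium pump SERCA from calcium transport, went from 2.86 ± 0.942 to 28.1 ± 21.6 CPM (SD, n = 7 each), a 9.80-fold rise (log2 3.29 ± 0.43, SE, adjusted p = 8.64e-06). Atp2a2, the SERCA pump of slow muscle, rose from 502 ± 85.8 to 965 ± 201 CPM (log2 0.94 ± 0.17, adjusted p = 0.000291). Chrnd (ENSRNOG00000019527), the delta subunit of the acetylcholine receptor, rose 2.94-fold, from 25.2 ± 5.02 to 74.3 ± 13.0 CPM (log2 1.56 ± 0.14, adjusted p = 4.87e-09). Gpd1 (ENSRNOG00000056457), the cytosolic glycerol-3-phosphate dehydrogenase of fast fibres, fell from 1556 ± 231 to 867 ± 94.2 CPM (log2 -0.84 ± 0.10, adjusted p = 1.64e-06). Each gene named as higher or lower in this comparison was so in 7 of 7 control_4C libraries, set against the control_RT mean, except Pdk4 (6 of 7).

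Of 15 tested genes of the slow oxidative fibre list, 13 rose and 0 fell, both over all genes and adjusted over the list alone, with a median log2 change of 0.94. They included Myh7, the slow myosin heavy chain (0.79 ± 0.19, adjusted p = 0.00294), Tpm3, the slow tropomyosin (0.94 ± 0.17, adjusted p = 0.000205), and Myoz2, a slow-fibre Z-disc protein (0.97 ± 0.17, adjusted p = 0.000257). Camera gave the list an adjusted p = 7.84e-09, and adjusted p = 0.225 with an estimated correlation. In the fast glycolytic fibre list 8 of 14 genes fell and 0 rose over all genes, and 11 fell adjusted over the list alone. Its camera adjusted p = 7.14e-08 became adjusted p = 0.258 with an estimated correlation. Actn3, the fast-fibre actinin of the Z-disc, fell by 0.74 ± 0.11 on the log2 scale (adjusted p = 4.32e-05). Myoz1, its binding partner, fell by 0.55 ± 0.08 (adjusted p = 3.91e-05). Myh1, the fast IIx myosin, was at log2 -0.37 ± 0.15 (adjusted p = 0.0833), or -0.45 without control_RT replicate 4 (adjusted p = 0.0307) and -0.37 without column KO8 (adjusted p = 0.0363). In the calcium cycling list 4 of 21 genes rose and 5 fell (4 and 7 adjusted over the list alone). Phospholamban (Pln), another SERCA regulator, was among those that rose (0.65 ± 0.17, adjusted p = 0.00476). Ryr1, the calcium release channel, was at -0.43 ± 0.19 (adjusted p = 0.114), or -0.44 without column KO8 of another group (adjusted p = 0.00999).

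Fatty acid uptake and oxidation genes rose in 10 of 22 cases over all genes, and 10 rose and 1 fell adjusted over the list alone. Camera called them upward (adjusted p = 0.00199, and adjusted p = 0.282 with an estimated correlation). Etfa, which passes electrons from fat oxidation to the respiratory chain, rose by log2 1.25 ± 0.23 (adjusted p = 0.000289), and Acsl1, which activates long-chain fatty acids, by 0.59 ± 0.10 (adjusted p = 0.000129). Glycolysis and glycogen genes fell in 12 of 24 cases and rose in 2 (14 and 3 adjusted over the list alone). Camera called them downward (adjusted p = 0.000170, and adjusted p = 0.258 with an estimated correlation). Among them were Aldoa, the muscle aldolase, at -0.54 ± 0.09 (adjusted p = 5.73e-05) and Slc16a3, the lactate exporter, at -0.61 ± 0.10 (adjusted p = 5.85e-05). The transcripts of the mitochondrial genome moved against the fat oxidation genes: 9 of 12 fell and 0 rose under both adjustments. Their camera adjusted p = 5.40e-08 became adjusted p = 0.225 with an estimated correlation, and control_RT replicate 6 stood apart above its group for this list. Mt-nd5, a complex I subunit, fell by 0.79 ± 0.11 (adjusted p = 8.31e-06), and Mt-co3, a complex IV subunit, by 0.77 ± 0.11 (adjusted p = 1.95e-05). Nuclear genes of oxidative phosphorylation rose in 3 and fell in 5 of 40 cases (camera adjusted p = 0.0632). Ucp2, a relative of UCP1 in the inner mitochondrial membrane, rose by 1.44 ± 0.26 (adjusted p = 0.000226). Ucp3 was at -0.41 ± 0.30 (adjusted p = 0.363), or -0.77 without control_4C replicate 4 (adjusted p = 0.0438). Ppargc1a, the coactivator of mitochondrial biogenesis, was at -0.05 ± 0.23 (adjusted p = 0.898). Pdk4, the kinase that shuts pyruvate out of the citric acid cycle, fell by 0.85 ± 0.30 (adjusted p = 0.0405). This call ended without any of 9 single libraries (log2 -1.03 to -0.69 over all libraries left out in turn).

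Genes of several other programs rose. The satellite cell, regeneration and denervation list had 6 of 14 genes higher and 1 lower under both adjustments (camera adjusted p = 0.0281, adjusted p = 0.282 with an estimated correlation). Among them were Gadd45a, induced in denervated muscle (1.22 ± 0.16, adjusted p = 6.65e-06), and Cdkn1a, the cell-cycle inhibitor p21 (2.04 ± 0.36, adjusted p = 0.000250). Glucocorticoid-responsive genes rose in 7 of 14 cases and 8 adjusted over the list alone (camera adjusted p = 0.00119, adjusted p = 0.225 with an estimated correlation). Klf15, a transcription factor of amino acid catabolism, rose by 1.30 ± 0.22 (adjusted p = 0.000173). Macrophage and leukocyte markers rose in 6 of 16 cases and 7 adjusted over the list alone (camera adjusted p = 0.000164, adjusted p = 0.258 with an estimated correlation). These included Lyz2 (0.99 ± 0.14, adjusted p = 1.66e-05) and the scavenger receptor Cd163 (1.04 ± 0.20, adjusted p = 0.000312). Spp1, the secreted protein osteopontin, rose by 2.42 ± 0.51 (adjusted p = 0.00118). Clock genes rose in 7 of 15 cases and fell in 2 (8 and 2 adjusted over the list alone, camera adjusted p = 0.0245, adjusted p = 0.225 with an estimated correlation). Dbp, a clock output factor, rose by 1.95 ± 0.30 (adjusted p = 5.85e-05), and its antagonist Nfil3 fell by 1.22 ± 0.28 (adjusted p = 0.00205). The time of day of sampling did not enter the fit, so any difference in it cannot be told apart from cold for these genes. Fos, an immediate-early transcription factor, fell by 1.88 ± 0.34 (adjusted p = 0.000310).

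Markers of other cells and stress genes moved in the same contrast as the transcript-loss index, which stood 7 libraries against 7 without overlap. Erythroid genes rose in 5 of 7 cases and 6 adjusted over the list alone (camera adjusted p = 0.00401, adjusted p = 0.258 with an estimated correlation). Hbb, a beta globin, rose by 3.07 ± 0.60 (adjusted p = 0.000662), or by 2.30 without control_4C replicate 2 (adjusted p = 0.00271), which stood apart above its group. Adipocyte markers rose in 5 of 11 cases under both adjustments (camera adjusted p = 0.00197, adjusted p = 0.258 with an estimated correlation). The fatty acid carrier Fabp4 rose by 1.16 ± 0.15 (adjusted p = 2.60e-06). Smooth muscle markers rose in 5 of 11 cases and 7 adjusted over the list alone (camera adjusted p = 0.0245, adjusted p = 0.258 with an estimated correlation). Fibroblast and matrix genes rose in 7 of 19 cases and 8 adjusted over the list alone (camera adjusted p = 0.0358, adjusted p = 0.387 with an estimated correlation). Tendon genes rose in 2 of 10 cases and fell in 1 under both adjustments (camera adjusted p = 0.0447, adjusted p = 0.387 with an estimated correlation). Heat shock genes rose in 4 of 16 cases and fell in 1 under both adjustments (camera adjusted p = 0.0342, adjusted p = 0.258 with an estimated correlation). The small chaperone Hspb7 rose by 1.07 ± 0.21 (adjusted p = 0.000464) and the cold-inducible RNA-binding protein Rbm3 by 0.68 ± 0.13 (adjusted p = 0.000433). Oxidative stress genes rose in 4 of 14 cases and 5 adjusted over the list alone (camera adjusted p = 0.0358, adjusted p = 0.258 with an estimated correlation). The peroxidase Gpx1 rose by 0.99 ± 0.12 (adjusted p = 2.26e-06). Left-out sets of libraries or counts divided by 2 ended the calls of the tendon (adjusted p = 0.0534 to 0.0805), fibroblast and matrix (0.0646 to 0.116), heat shock (0.0582 and 0.0631), oxidative stress (0.0536 to 0.0776) and smooth muscle lists (0.0505).

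Lists without a camera call after cold in control rats were, with the adjusted p of each, citric acid cycle (0.238), PPAR and fasting (0.10), lipid synthesis (0.238), creatine cycle (0.687), mitochondrial biogenesis (0.317), brown adipocyte (0.655, 2 genes tested), endothelial (0.187), Schwann cell (0.602), atrophy and autophagy (0.294), thyroid hormone (0.198), calcium cycling (0.340), immediate-early (0.540), unfolded protein (0.793), interferon (0.793) and ribosomal protein (0.796). The median, the mean and the test differed in sign for the calcium cycling, unfolded protein, interferon and ribosomal protein lists.

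Over all genes, 2399 of 11594 passed the threshold for cold in control rats, 1439 higher and 960 lower, and 534 of them changed at least 2-fold (456 higher, 78 lower). With the loss index as a covariate 444 genes passed, 190 higher and 254 lower. Cyr61, a matrix-associated signalling protein, went from 2.77 ± 0.66 (adjusted p = 0.00342) to 0.04, while Sln kept its call at 1.95 (adjusted p = 0.0225). The heat shock, oxidative stress and smooth muscle list calls ended with this covariate (adjusted p = 0.155, 0.493 and 0.116). The calls of Hbb (to 1.23 ± 0.53), Etfa (0.44 ± 0.17), Klf15 (0.59 ± 0.19) and Acsl1 (0.35 ± 0.11) ended with smaller changes. Those of Spp1 (2.35 ± 0.72), Nfil3 (-1.06 ± 0.35), Atp2a2 (0.69 ± 0.21), Myoz2 (0.67 ± 0.21), Myh7 (0.59 ± 0.24), Pln (0.45 ± 0.21) and Pdk4 (-0.54 ± 0.37) ended with larger standard errors as well. With the slow-fibre list as a covariate 239 genes passed, 100 higher and 139 lower. It ended the calls of its own members Myh7, Tpm3, Atp2a2 and Myoz2, as it would by construction. Sln kept its call (2.75, adjusted p = 0.0204). The calls of Cyr61 (0.91 ± 0.91), Etfa (0.48 ± 0.30), Klf15 (0.74 ± 0.31) and Acsl1 (0.26 ± 0.13) ended with smaller changes. Those of Spp1 (2.45 ± 0.84), Hbb (2.60 ± 0.97), Pln (0.56 ± 0.26) and Nfil3 (-0.94 ± 0.41) ended with changes nearer those of the main fit and larger standard errors. The calls of Pdk4 (-0.40 ± 0.44), Actn3 (-0.56 ± 0.17), Ucp2 (1.02 ± 0.38), Aldoa (-0.46 ± 0.13), Slc16a3 (-0.49 ± 0.15), Rbm3 (0.55 ± 0.19) and Hspb7 (0.61 ± 0.28) ended too.

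In knockout rats Sln rose 8.04-fold with cold, from 3.73 ± 2.12 to 30.6 ± 8.81 CPM (SD, n = 9 each, log2 3.01 ± 0.37, SE, adjusted p = 1.49e-06). Chrnd rose 3.06-fold (log2 1.61 ± 0.13, adjusted p = 5.0e-11). Lpl (ENSRNOG00000012181), the lipase that frees fatty acids from circulating triglyceride, rose 2.49-fold, from 273 ± 58.4 to 679 ± 187 CPM (log2 1.32 ± 0.13, adjusted p = 2.37e-08). Spp1 rose by log2 3.17 ± 0.48 (adjusted p = 2.92e-05) and Cdkn1a by 2.53 ± 0.32 (adjusted p = 2.43e-06). Among the genes that fell, Tead1, a transcription factor of muscle genes, dropped by 1.39 ± 0.16 (adjusted p = 2.63e-07), Col1a1, a type I collagen chain, by 1.62 ± 0.31 (adjusted p = 0.000523), and Tfrc, the transferrin receptor, by 1.25 ± 0.17 (adjusted p = 4.06e-06). Each gene named as higher or lower in this comparison was so in 9 of 9 KO_4C libraries, set against the KO_RT mean, except Myh7 and Myh1 (8 of 9 each).

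The slow oxidative fibre list had 11 of 15 genes higher and 0 lower under both adjustments, with a median of 0.75 (camera adjusted p = 5.59e-08, adjusted p = 0.160 with an estimated correlation). Atp2a2 rose by 0.80 ± 0.15 (adjusted p = 0.000382), Csrp3, a Z-disc stretch sensor, by 1.09 ± 0.19 (adjusted p = 0.000173), Pln by 0.72 ± 0.15 (adjusted p = 0.000697) and Myh7 by 0.58 ± 0.17 (adjusted p = 0.0155). In the fast glycolytic fibre list 5 of 14 genes fell under both adjustments (camera adjusted p = 0.000217, adjusted p = 0.311 with an estimated correlation). Actn3 stood at -0.66 ± 0.10 (adjusted p = 1.96e-05) and Myh1 at -0.47 ± 0.13 (adjusted p = 0.0164). Ryr1 fell by 1.08 ± 0.17 (adjusted p = 5.35e-05). Column KO8 stood apart above the other KO_RT libraries for the fast-fibre list, Actn3, Myh1 and Ryr1. Cacna1s, the voltage sensor that opens the Ryr1 channel, fell by 0.75 ± 0.13 (adjusted p = 8.32e-05). The calcium cycling list, which holds Ryr1 and Cacna1s, had no camera call in knockout rats.

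Fat oxidation genes rose in 11 of 22 cases and 13 adjusted over the list alone (camera adjusted p = 7.26e-08, adjusted p = 0.0989 with an estimated correlation). Cpt2, which readies fatty acids for oxidation inside mitochondria, rose by 0.60 ± 0.09 (adjusted p = 1.0e-05). The PPAR and fasting list had 5 of 15 genes higher and 1 lower under both adjustments (camera adjusted p = 0.0136, adjusted p = 0.229 with an estimated correlation). It included Plin5, which couples lipid droplets to mitochondria (1.11 ± 0.14, adjusted p = 5.85e-07), Lipe, the hormone-sensitive lipase (0.79 ± 0.11, adjusted p = 3.03e-06), and Ucp2 (1.40 ± 0.23, adjusted p = 4.98e-05). Ucp3 stood at 0.28 ± 0.26 (adjusted p = 0.542), Pdk4 at -0.02 ± 0.27 (adjusted p = 0.967) and Ppargc1a at -0.55 ± 0.20 (adjusted p = 0.0634), which passed without any of 4 single libraries. Mitochondrial DNA-encoded transcripts fell in 6 of 12 cases, and 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 7.26e-06, adjusted p = 0.190 with an estimated correlation). Glycolysis genes fell in 8 of 24 cases and rose in 3 (9 and 3 adjusted over the list alone, camera adjusted p = 0.00277, adjusted p = 0.311 with an estimated correlation). Slc16a3 stood at -0.62 ± 0.09 (adjusted p = 4.06e-06) and Pygm, the muscle glycogen phosphorylase, at -0.46 ± 0.08 (adjusted p = 6.05e-05). Prkaa2, the catalytic AMPK subunit of muscle, fell by 0.65 ± 0.08 (adjusted p = 5.85e-07).

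Endothelial markers rose in 6 of 14 cases and 10 adjusted over the list alone (camera adjusted p = 5.58e-06, adjusted p = 0.0989 with an estimated correlation). The junction protein Esam rose by 0.81 ± 0.10 (adjusted p = 5.85e-07) and the VEGF receptor Flt1 by 0.77 ± 0.13 (adjusted p = 5.80e-05). Macrophage markers rose in 7 of 16 cases and 9 adjusted over the list alone (camera adjusted p = 7.26e-06, adjusted p = 0.190 with an estimated correlation). Lyz2 rose by 1.12 ± 0.13 (adjusted p = 2.24e-07). Atrophy and autophagy genes rose in 8 of 23 cases and fell in 2 (10 and 2 adjusted over the list alone, camera adjusted p = 0.0264, adjusted p = 0.229 with an estimated correlation). Gabarapl1, an autophagosome protein, rose by 0.70 ± 0.10 (adjusted p = 6.50e-06), and Igfbp5, which binds insulin-like growth factors, fell by 0.99 ± 0.17 (adjusted p = 9.08e-05). The satellite cell and denervation list had 5 of 14 genes higher (camera adjusted p = 0.00115, adjusted p = 0.160 with an estimated correlation). The glucocorticoid list had 4 of 14 (camera adjusted p = 0.000190, adjusted p = 0.0989 with an estimated correlation) and the oxidative stress list 4 of 14 (camera adjusted p = 0.000784, adjusted p = 0.0989 with an estimated correlation). These 3 lists had the same counts adjusted over each list alone. The antioxidant enzymes Nqo1 and Hmox1 rose, Nqo1 by 0.73 ± 0.10 (adjusted p = 4.06e-06) and Hmox1 by 1.11 ± 0.16 (adjusted p = 6.49e-06). Single libraries stood apart below the others of KO_RT for Flt1 (KO10), Nqo1 (KO15) and Hmox1 (KO8). Heat shock genes rose in 6 of 16 cases and fell in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00158, adjusted p = 0.0989 with an estimated correlation). The chaperone Hspb8 rose by 0.84 ± 0.13 (adjusted p = 1.92e-05). Erythroid genes rose in 2 of 7 cases and 6 adjusted over the list alone (camera adjusted p = 0.000810, adjusted p = 0.198 with an estimated correlation). Adipocyte markers rose in 2 of 11 under both adjustments (camera adjusted p = 0.0136, adjusted p = 0.311 with an estimated correlation). Smooth muscle (adjusted p = 0.0869), fibroblast and matrix (0.707), tendon (0.494) and clock genes (0.328) had no camera call in knockout rats.

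Over all genes, 1596 passed for cold in knockout rats, 868 higher and 728 lower, and 186 changed at least 2-fold (117 higher, 69 lower). With the slow-fibre list as a covariate 463 passed, 210 higher and 253 lower, and the calls of its members Csrp3, Atp2a2 and Myh7 ended, as they would by construction. Those of Flt1 (0.52 ± 0.17), Pln (0.64 ± 0.21) and Myh1 (-0.44 ± 0.19) ended with larger standard errors. The loss index stood at 5.50 ± 0.90 and 5.96 ± 0.17 in the groups compared (exact permutation p = 0.175). Column KO10, low on it by construction, is part of KO_RT, so this p does not test the groups cleanly. With the loss index as a covariate the calls of the PPAR list (adjusted p = 0.0601), Myh7 (0.51 ± 0.18) and Myh1 (-0.35 ± 0.13) ended. The PPAR call also ended without the 4 libraries lowest on the index (adjusted p = 0.0534), and the atrophy call with the intestinal markers as a covariate (adjusted p = 0.0769).

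**Figure D2:**
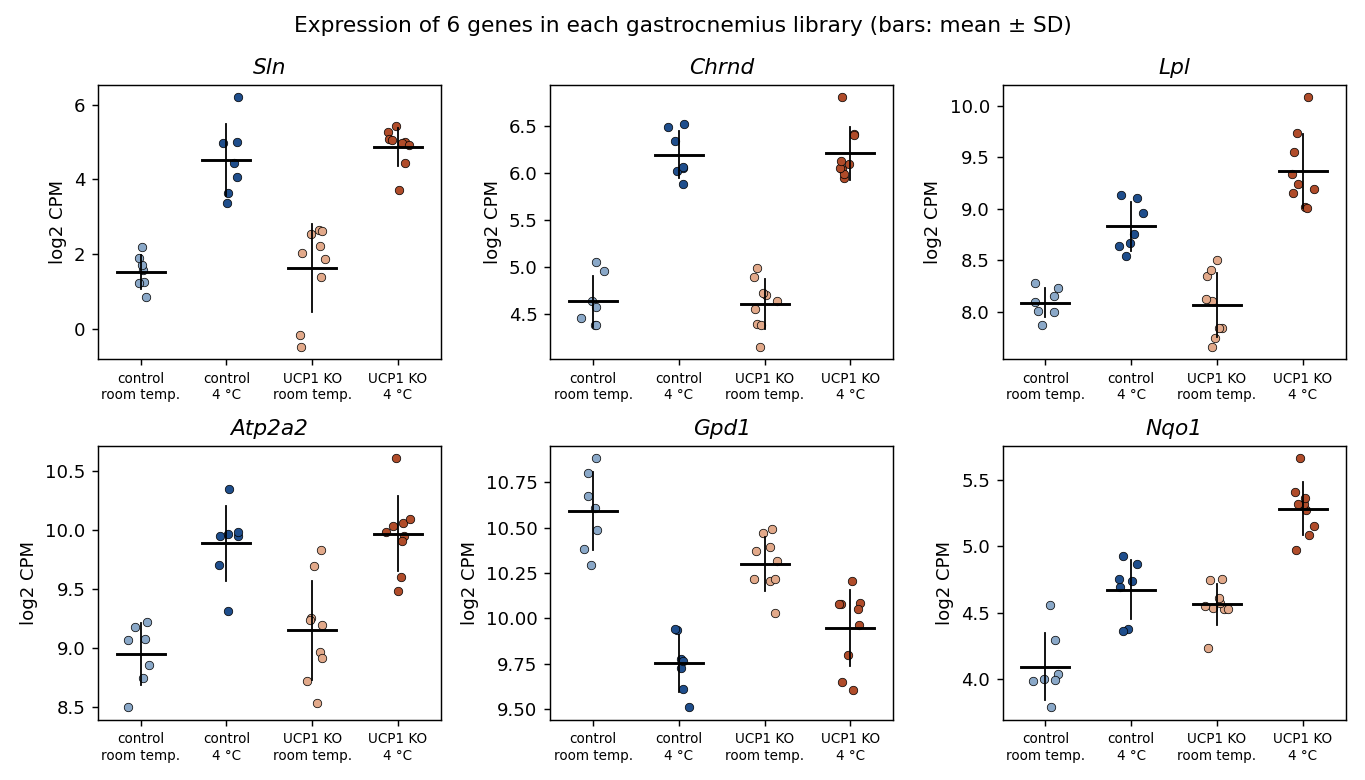
Expression of 6 genes in each library by group, as log2 CPM; points are libraries, and bars give the mean ± SD. Sln, Chrnd, Lpl and Atp2a2 were higher and Gpd1 lower at 4 °C in both genotypes, and Nqo1 was highest in KO_4C (39.2 ± 5.60 CPM, n = 9).

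**Figure D3:**
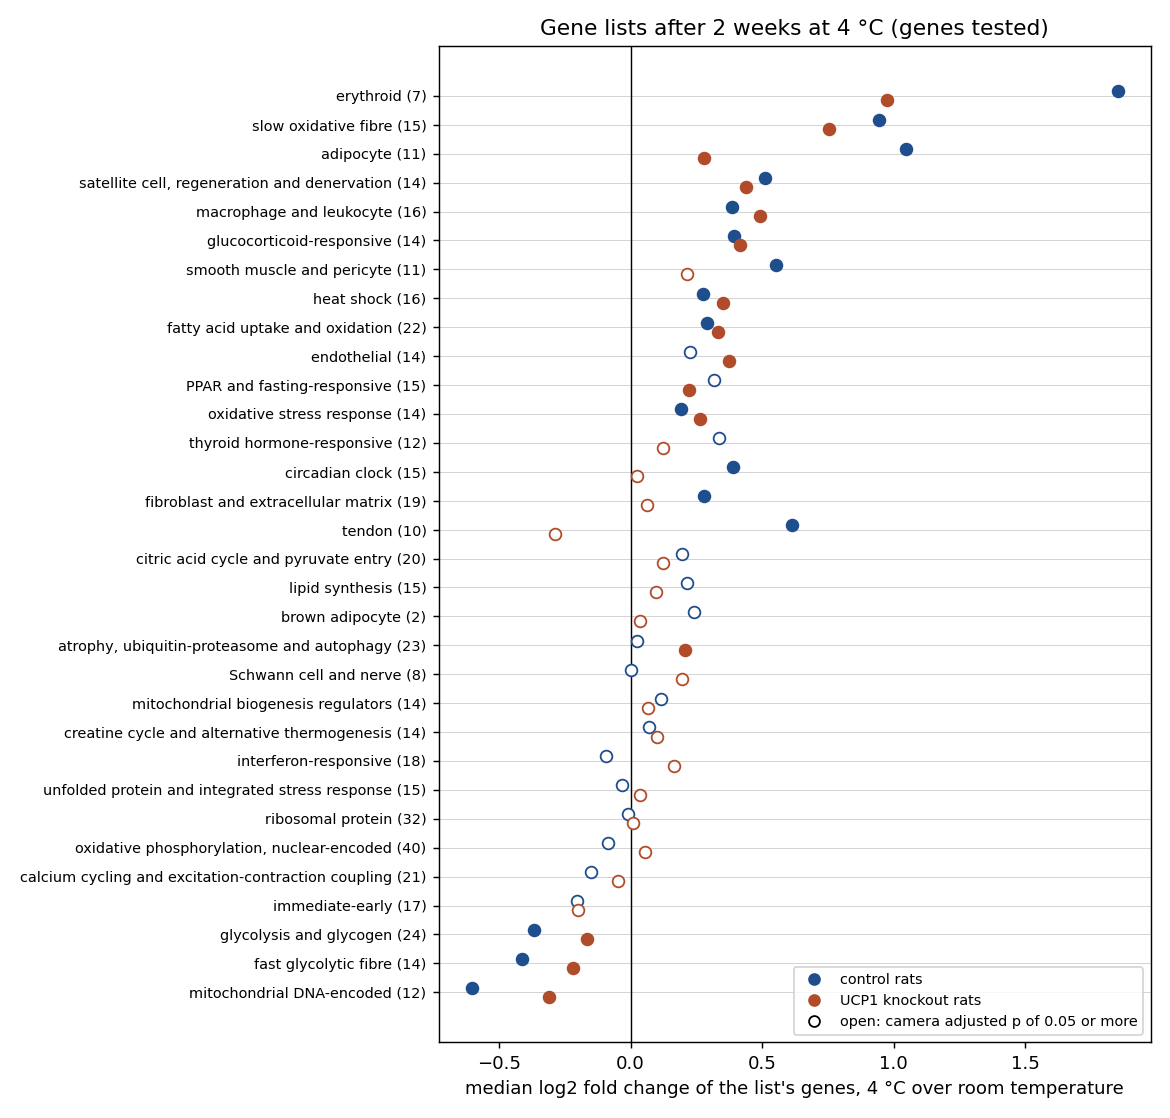
Median log2 fold change of each gene list, 4 °C over room temperature, in control rats (blue) and knockout rats (red); filled points had a camera adjusted p under 0.05, and the number of genes tested stands in brackets. The slow oxidative fibre list had medians of 0.94 and 0.75, and the mitochondrial DNA-encoded list of -0.60 and -0.31.

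The responses of the 2 genotypes to cold, which share no library, were alike in direction. Across the genes tested, which are not independent replicates, their log2 fold changes had a Pearson r of 0.495 and a Spearman rho of 0.512. Of the genes called in both genotypes, 398 were higher in both (107.7 expected for independent lists), 386 lower in both (60.3 expected) and 1 went in opposite directions. Sln, Chrnd, Spp1, Cdkn1a and Gpx1 were among those higher in both, and Gpd1, Actn3 and Aldoa among those lower in both. Of the genes called in control rats, 89.3% had the same sign in knockout rats. Without columns KO8 and KO10 the r was 0.354, and among genes of at least 10 CPM it was 0.633. Both room-temperature groups held libraries low on the loss index, so part of the likeness may come from it. Of called genes at least 2-fold higher with cold in control rats, 87.5% were lower in KO8 and KO10 than in the other KO_RT libraries. In knockout rats, whose comparison includes these columns, the share was 70.9%. With the index as a covariate the r was 0.397.

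**Figure D4:**
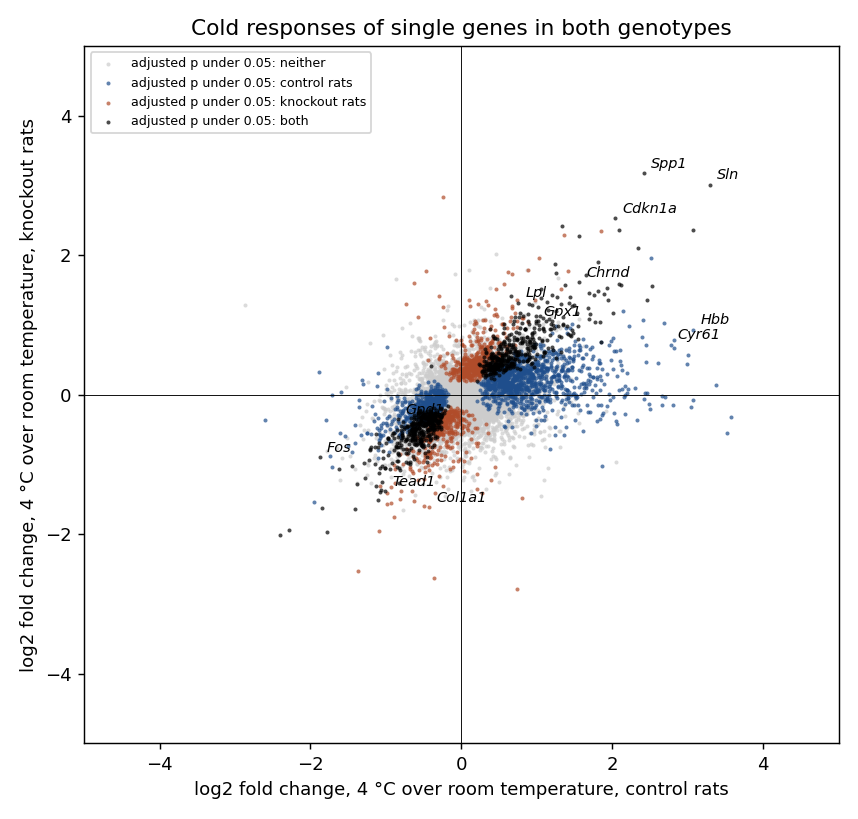
Log2 fold change of each tested gene, 4 °C over room temperature, in control rats (horizontal) and knockout rats (vertical), coloured by the genotype in which its adjusted p was under 0.05. The genes past the threshold in both genotypes, in black, lie in the upper right (398) and lower left (386) with 1 exception.

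At room temperature Cyr61 rose 8.07-fold in knockout muscle, from 12.7 ± 9.76 CPM in control_RT (SD, n = 7) to 104 ± 82.9 in KO_RT (n = 9, log2 3.01 ± 0.65, SE, adjusted p = 0.0130, higher in 7 of 9 libraries). F3, the tissue factor that starts blood clotting, rose by log2 2.18 ± 0.49 (adjusted p = 0.0169, 7 of 9), and Nr4a1, an orphan nuclear receptor induced by contraction, by 2.15 ± 0.47 (adjusted p = 0.0145, 7 of 9). Acat1, the acetyl-CoA acetyltransferase of ketone use, rose by 1.07 ± 0.19 (adjusted p = 0.00910), Acadm, the medium-chain acyl-CoA dehydrogenase, by 0.62 ± 0.12 (adjusted p = 0.00936), and Sdhd, an anchor subunit of complex II, by 1.31 ± 0.24 (adjusted p = 0.00936, 8 of 9). The cytoskeletal linker Dst rose by 0.61 ± 0.10 (adjusted p = 0.00478). Genes that fell included Mrps6, a mitochondrial ribosomal protein (-0.46 ± 0.11, adjusted p = 0.0162), and Ndufb8, a complex I subunit (-0.32 ± 0.08, adjusted p = 0.0206). Acat1, Acadm and Dst were higher, and Mrps6 and Ndufb8 lower, in 9 of 9 libraries. Without control_RT replicate 3 neither Mrps6 nor Ndufb8 passed (adjusted p = 0.0511 and 0.0648), nor did Mrps6 without control_RT replicate 2 (adjusted p = 0.0602).

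The only list called by camera was the citric acid cycle, where 1 of 20 genes rose over all genes and 6 adjusted over the list alone (adjusted p = 0.0425, adjusted p = 0.927 with an estimated correlation). Its called member was Fh, fumarase (0.97 ± 0.23, adjusted p = 0.0206, 7 of 9, 0.0661, 0.0579 and 0.0517 without control_RT replicate 2 or 3 or column KO16). Fatty acid oxidation had 4 of 22 genes higher, and 6 adjusted over the list alone (camera adjusted p = 0.0628). Nqo1 rose by 0.46 ± 0.11 (adjusted p = 0.0190) in 9 of 9 libraries. This call ended without control_RT replicate 2, 3, 5 or 6 (adjusted p = 0.0620, 0.0706, 0.0502 and 0.0519). Sln (0.40 ± 0.41, adjusted p = 0.680), Ucp2 (-0.00 ± 0.25, adjusted p = 0.997), Ucp3 (-0.24 ± 0.28, adjusted p = 0.728) and Myh7 (0.21 ± 0.18, adjusted p = 0.594) did not pass. Over all genes 303 passed, 273 higher and 30 lower. Beside these, the loss index stood at 4.71 ± 0.57 in control_RT and 5.50 ± 0.90 in KO_RT (two-sided exact permutation p = 0.0657). As KO_RT includes column KO10, low on the index by construction, this p does not test the groups cleanly. Further, 93.8% of the genes called higher were lower in KO8 and KO10 than in the other KO_RT libraries, against 48.8% of genes not called. The count was 1 with the loss index as a covariate, which also ended the citric acid cycle call (adjusted p = 0.658), 708 without the 4 libraries lowest on the loss index (588 higher, 120 lower), 1541 without columns KO8 and KO10 (1009 higher, 532 lower), and 573 in DESeq2. With either set left out, the index did not overlap between the genotypes. With the index as a covariate Cyr61 stood at 0.57 ± 0.35, F3 at 0.69 ± 0.40, Nr4a1 at 0.30 ± 0.29, Sdhd at 0.52 ± 0.13 and Acadm at 0.31 ± 0.09. Nqo1 (0.38 ± 0.11) and Ndufb8 (-0.31 ± 0.09) stayed nearer their changes in the main fit. The citric acid cycle call also ended with the intestinal markers as a covariate (adjusted p = 0.0633). In edgeR on these 2 groups alone the count was 0 (1685 at an unadjusted p under 0.05), and leaving out single libraries gave 80 (without control_RT replicate 3) to 792 (without column KO10).

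At 4 °C 6 genes passed the threshold between the genotypes in the main fit. An unadjusted p under 0.05 in edgeR was reached by 1695 of 11594, and the count past the threshold changed with the processing. Nqo1 (ENSRNOG00000012772), the quinone reductase of the antioxidant response, was 1.5-fold higher in knockout muscle, 39.2 ± 5.60 CPM (SD, n = 9) against 25.6 ± 3.83 (n = 7, log2 0.61 ± 0.11, SE, adjusted p = 0.0262). Klhl38, a kelch protein of muscle, was 1.5-fold higher (0.62 ± 0.12, adjusted p = 0.0292), Best3, a bestrophin chloride channel, 1.6-fold (0.68 ± 0.14, adjusted p = 0.0499), and the serine kinase Pskh1 1.3-fold (0.39 ± 0.08, adjusted p = 0.0499). Tmem102 (-1.44 ± 0.28, adjusted p = 0.0362) and Sult1d1, a sulfotransferase (-1.32 ± 0.27, adjusted p = 0.0499), were lower. Both lie outside the rule for named genes and were chosen after their values were seen. Each of these 6 genes lay on its side of the control_4C mean in 9 of 9 KO_4C libraries. Sln (0.12 ± 0.35, adjusted p = 0.933), Ucp2 (-0.04 ± 0.23, adjusted p = 0.973), Ucp3 (0.44 ± 0.28, adjusted p = 0.511) and Myh7 (0.00 ± 0.18, adjusted p = 0.998) did not pass.

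Camera called 10 lists at 4 °C, none of which passed with an estimated correlation, and no member of them passed over all genes. Higher in knockout muscle were fatty acid oxidation (median 0.24, adjusted p = 8.41e-07, adjusted p = 0.310 with an estimated correlation), endothelial markers (0.23, adjusted p = 0.000909, adjusted p = 0.310 with an estimated correlation), nuclear-encoded oxidative phosphorylation (0.12, adjusted p = 0.00167, adjusted p = 0.561 with an estimated correlation) and mitochondrial DNA-encoded transcripts (0.18, adjusted p = 0.00734, adjusted p = 0.561 with an estimated correlation). The citric acid cycle (0.11, adjusted p = 0.00391), glycolysis (0.16, adjusted p = 0.00588) and atrophy lists (0.15, adjusted p = 0.0184) were higher as well, with adjusted p = 0.561, 0.561 and 0.475 with an estimated correlation. Lower were fibroblast and matrix genes (median -0.17, adjusted p = 0.00312), macrophage markers (-0.26, adjusted p = 0.00705) and ribosomal protein genes (-0.09, adjusted p = 0.0106), with adjusted p = 0.514, 0.561 and 0.619 with an estimated correlation. Adjusted over the list alone, 2 fatty acid oxidation genes, 2 endothelial genes, 2 citric acid cycle genes and 1 atrophy gene were higher, and 1 ribosomal protein gene was lower. Beside these lists, all 26 intestinal epithelial markers tested had a negative log2 change (median -1.03), 25 of them with an unadjusted p under 0.05 and 0 past the threshold in edgeR (smallest adjusted p = 0.0506). The abundant marker Lgals4, a galectin of gut epithelium, stood at 637 and 530 CPM in control_4C replicates 3 and 6 against a median of 181 in the other libraries. With the intestinal markers as a covariate, the oxidative phosphorylation, mitochondrial DNA-encoded, citric acid cycle, glycolysis, atrophy, endothelial and macrophage calls ended (adjusted p = 0.293, 0.592, 0.208, 0.855, 0.592, 0.081 and 0.075), and glycolysis turned downward. Without the 3 libraries highest in these markers the glycolysis, macrophage, atrophy and ribosomal protein calls ended (adjusted p = 0.180, 0.0791, 0.110 and 0.0960). Over all genes 6 passed, 4 higher and 2 lower. The count was 0 in edgeR without the 3 libraries highest in intestinal markers (628 at an unadjusted p under 0.05) or on these 2 groups alone (1733), against 432 in DESeq2. Leaving out single libraries gave 0 to 556. The call of Nqo1 ended without control_4C replicate 6 or KO_4C replicate 4 or 7 (adjusted p = 0.138, 0.0601 and 0.0586), that of Klhl38 without any of 6 single libraries, and those of Best3, Pskh1, Tmem102 and Sult1d1 without any of 21, 20, 9 and 22. With RLE factors 121 genes passed, of which 9.09% were higher.

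The interaction tests whether the response to cold itself differs between genotypes. Klhl38 was the gene called in opposite directions: it fell with cold in control rats (log2 -0.41, adjusted p = 0.0158) and rose in knockout rats (0.42, adjusted p = 0.00714), a difference of 0.82 ± 0.16 (SE, adjusted p = 0.0479). Asah2, a neutral ceramidase, rose in control rats (1.02, adjusted p = 0.000291) and stood at -0.25 in knockout rats (adjusted p = 0.348), a difference of -1.28 ± 0.25 (adjusted p = 0.0479). LOC100360316, an unnamed locus, had a difference of -1.34 ± 0.25 (adjusted p = 0.0441). It lies outside the rule for named genes and was chosen after its values were seen. Sln showed no detectable difference (-0.28 ± 0.54, adjusted p = 0.869). Camera called the fast glycolytic fibre (median difference 0.16, adjusted p = 0.00801), nuclear-encoded oxidative phosphorylation (0.17, adjusted p = 0.00517), mitochondrial DNA-encoded (0.21, adjusted p = 0.0262) and endothelial lists (0.25, adjusted p = 0.00801) upward, that is, less decline or more rise with cold in knockout rats. Fibroblast and matrix genes went the other way (-0.31, adjusted p = 0.00517). With an estimated correlation these were adjusted p = 0.842, 0.842, 0.842, 0.692 and 0.692, and no member passed over all genes. The 4 upward calls ended with the intestinal markers as a covariate (adjusted p = 0.237, 0.159, 0.361 and 0.189). The mitochondrial and endothelial calls also ended without the 3 libraries highest in these markers (adjusted p = 0.0571 and 0.171) or the 4 lowest on the loss index (0.221 and 0.0807). The mitochondrial and matrix calls ended without columns KO8 and KO10 (adjusted p = 0.276 and 0.0709), and the fast-fibre call with the loss index as a covariate (0.188). Adjusted over the list alone 1 fast-fibre and 1 endothelial gene were higher and 1 matrix gene was lower. Over all genes Klhl38, Asah2 and LOC100360316 were all that passed, against 106 in DESeq2, 725 without columns KO8 and KO10, and 0 to 226 when single libraries were left out. Without the 3 libraries highest in intestinal markers LOC100360316 alone of these kept its call, and with the loss index as a covariate Klhl38 alone did. The calls of Klhl38, Asah2 and LOC100360316 ended without any of 23, 21 and 17 single libraries, with differences of 0.77 to 0.88, -1.37 to -1.09 and -1.41 to -1.22.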

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

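The tests of transcript loss, of like size at 4 °C, of intestinal RNA, of misassigned reads, of the ratio of Sln to Myh7 and of the spread of the slow isoforms were chosen after the results were seen. The test of sign at 4 °C and the counts over other splits of the samples were written down before their results were seen.

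The first pattern is that 273 of 303 genes called at room temperature were higher in knockout muscle. Loss of a set of transcripts from some room-temperature libraries is a candidate explanation: 93.8% of the genes called higher were lower in columns KO8 and KO10 than in the other KO_RT libraries, against 48.8% of genes not called, and the loss index as a covariate left 1 gene. With it some changes shrank (Cyr61 from log2 3.01 to 0.57, Sdhd from 1.31 to 0.52). Others stayed near their size though their calls ended (Nqo1 from 0.46 to 0.38, Ndufb8 from -0.32 to -0.31). The count of 1 therefore does not show that the index accounts for every called gene. The control_RT libraries, replicates 2 and 3 most, carry the same mark (index 3.77 and 4.30). Without the 4 libraries lowest on the index the count rose to 708 (588 higher, 274 of the 303 kept), so these 4 alone did not make the pattern. The libraries left still differed by genotype on the index without overlap (at most 5.41 in control_RT, at least 5.64 in KO_RT). That count therefore cannot tell the index from the genotype. Against a genotype difference of like size at both temperatures, the genes called higher had a median log2 change of 0.86 at room temperature and of 0.0418 at 4 °C (SD 0.240 over the genes, and 0.643 for the difference between temperatures). Their selection at room temperature raises the first median, and these SDs run over genes, not animals. A difference of like size was therefore not excluded. A smaller one stays open, with one sign at both temperatures for 60.4% of the genes called (50.2% to 67.3% when each 4 °C library was left out, against 54.7% of all genes), and whether transcripts were lost or expressed at other levels was not tested.

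The second pattern is that intestinal epithelial transcripts were lower in knockout muscle at 4 °C, with a median of -1.03 over 26 markers, none of which another list holds. Reads misassigned from other libraries of the run would weigh most in small libraries, but over the 32 libraries the intestinal share had a Spearman rho of -0.0869 with the library total (permutation p = 0.635; Pearson r -0.184 with the log10 total, permutation p = 0.310; r -0.249 without the 2 libraries farthest from the median total). Within groups the rho was -0.643 in control_RT, -0.321 in control_4C, 0.350 in KO_RT and 0.133 in KO_4C, so that 5 such correlations were computed. Intestinal RNA in control_4C replicates 3 and 6 may account for part of the difference: without these libraries and control_RT replicate 4 the median was -0.40, short of the -0.3 set for the whole. The markers were also present outside these libraries (median 181 CPM for Lgals4 and 25.2 CPM for Guca2a). Whether what remains reflects intestinal RNA there or a difference between the genotypes in muscle cannot be told apart.

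The third pattern is the rise of Sln and of slow-fibre genes with cold. The log2 changes of the 7 slow isoform genes ran from 0.28 to 1.19 over both genotypes (SD 0.270 in control and 0.209 in knockout rats, within the 0.3 set for a larger share of slow-fibre muscle in the sample), so this explanation stays open for them. For Sln, the log2 ratio of Sln to Myh7 rose by 2.20 in control rats (two-sided exact permutation p = 0.000583) and by 2.64 in knockout rats (exact permutation p = 8.23e-05). This argues against a larger slow share as the whole cause if the added slow muscle has the ratio of the room-temperature samples. The ratio in such muscle was not measured, so the test does not exclude the explanation. With the slow-fibre list as a covariate Sln kept log2 changes of 2.75 (adjusted p = 0.0204) and 2.66 (adjusted p = 0.00123), and with the loss index it went from 3.29 to 1.95 in control rats (adjusted p = 0.0225) and from 3.01 to 2.70 in knockout rats (adjusted p = 9.79e-07). A regulated rise of Sln in cold muscle is a hypothesis that these tests leave standing, found and tested on the same data, and its size in control rats depends on the loss index.

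Other splits of the samples were counted for each contrast, 100 per contrast with the real one included. For cold in control rats 1 split reached the real count of 2399 (highest other 810) and for cold in knockout rats 1 reached 1596 (highest other 1). An accidental split of the samples is an unlikely source of these counts, as none of the other splits drawn reached them. In control rats the loss index separated the groups without overlap, so the splits cannot tell cold from the index. For knockout at 4 °C 1 reached 6 (highest other 1) and for the interaction 1 reached 3 (highest other 1). These small counts ran from 0 to 556 and from 0 to 226 when single libraries were left out. In the interaction 1 other split had 1625 genes at an unadjusted p under 0.05 in edgeR, against 1499 in the real one. An accidental split is therefore not excluded for these 2 contrasts. For knockout at room temperature 2 splits reached 303 (highest other 765). Another split gave 240 genes, with 2011 at an unadjusted p under 0.05 in edgeR against 1989 in the real one. The real count fell to 80 without control_RT replicate 3, so an accidental split is not excluded there. The split with 765 genes put all 4 libraries lowest on the loss index into one group, but the other splits that did so gave 0 genes, so the structure of the samples behind its count was not identified.

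Of 433 sets of values checked for a library far from its group, 28 had one; chance alone gives about 1 in 20. The figure given for each is the gap to the nearest library over the range of the group. Column KO8 had 7 of them: it was highest for Ryr1 (0.584), Myh1 (0.553), Actn3 (0.590), Pkm (0.616), Cog4 (0.647) and the fast glycolytic fibre list (0.495), and lowest for Hmox1 (0.549). In the other KO_RT columns Flt1 was lowest in KO10 (0.595) and Nqo1 in KO15 (0.563). In control_RT the highest were Hmox1 (0.572) and the erythroid list (0.648) in replicate 1, the intestinal share in replicate 4 (0.609) and the mitochondrial DNA-encoded list in replicate 6 (0.663), and Tagln was lowest in replicate 2 (0.605). In control_4C the highest were Ucp3 (0.585) and the PPAR and fasting list (0.619) in replicate 4, Hbb (0.703) and the erythroid list (0.797) in replicate 2, and the immediate-early list in replicate 3 (0.569). The lowest there were Slc16a3 in replicate 3 (0.624), Hmox1 in replicate 5 (0.635) and Tagln in replicate 6 (0.591). In KO_4C Hspb8 (0.551) and the ribosomal protein list (0.572) were highest and Gpx1 lowest (0.562) in replicate 7, the tendon list was highest (0.611) and Pygm lowest (0.617) in replicate 8, and LOC100360316 was lowest in replicate 9 (0.594).

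The interaction test called Klhl38 (0.82, adjusted p = 0.0479), Asah2 (-1.28, adjusted p = 0.0479) and LOC100360316 (-1.34, adjusted p = 0.0441). These calls ended without any of 23, 21 and 17 single libraries. Among lists, camera gave adjusted p = 0.00801 for fast glycolytic fibre, 0.00517 for nuclear-encoded oxidative phosphorylation, 0.0262 for mitochondrial DNA-encoded, 0.00801 for endothelial and 0.00517 for fibroblast and matrix genes, with adjusted p of 0.692 or more with an estimated correlation.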

How the results depend on the processing

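The counts for cold in control and knockout rats kept within 1.5 times of 2399 and 1596 under most settings, and those between genotypes did not. Counts divided by 2, left-out sets of libraries and the loss-index and intestinal covariates were chosen after seeing the data; where no construction explains a change, the cause was not tested. An adjusted p of 0.01, stricter by construction, gave 1209 and 799 genes for cold in control and knockout rats, 21 and 0 for knockout at room temperature and at 4 °C, and 0 for the interaction. In the same order, the slow-fibre covariate gave 239, 463, 185, 426 and 0, DESeq2 2692, 1842, 573, 432 and 106, 1 surrogate variable 1488, 1339, 507, 11 and 59, the loss-index covariate 444, 1334, 1, 214 and 7, the intestinal covariate 2515, 1623, 292, 0 and 1, and leaving out columns KO8 and KO10 2996, 1282, 1541, 119 and 725. Without the 4 libraries lowest on the loss index the counts were 2010, 1330, 708, 8 and 288, and without the 3 highest in intestinal markers 2092, 1670, 380, 0 and 3. For the interaction this last set and that of 7 genes with the loss index each held only 1 of the 3 genes of the main fit. For knockout at 4 °C and the interaction, RLE factors gave 121 and 3, factors without the 20 most abundant genes 125 and 1, no filter 3 and 1, and counts divided by 2 81 and 3. The share of genes higher at 4 °C went from 66.7% to 9.09% with RLE factors and 9.60% without the abundant genes. Groups fitted alone gave 0 for knockout at room temperature and 0 at 4 °C (1685 and 1733 genes at an unadjusted p under 0.05).

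Replicate numbers were not shown to pair the samples. Correlations of like numbers ran from -0.313 to 0.405 between the control groups (2 of 7 over 0.1) and from -0.153 to 0.416 between control_4C and KO_4C (4 of 7 over 0.1), and 1 and 2 libraries correlated best with their own number. Used as a block, they gave 2339 genes for cold in control rats, where the tendon list had a camera adjusted p = 0.0665 and the call of Pdk4 ended, and 0 for knockout at 4 °C (1292 at an unadjusted p under 0.05). No paired analysis was possible for cold in knockout rats, knockout at room temperature and the interaction because the titles and descriptions of the KO_RT samples number them differently.

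Leaving out single libraries gave 1806 to 2827 for cold in control rats and 1331 to 1709 for cold in knockout rats. For knockout at room temperature, 11 libraries moved the count of 303 by over 1.5 times: it was 104, 80, 159 and 180 without control_RT replicates 2, 3, 5 and 6, and 777, 159, 792, 161, 197, 120 and 164 without columns KO8, KO9, KO10, KO13, KO15, KO16 and KO17. For knockout at 4 °C, 29 libraries moved the count of 6: it was 289, 269 and 100 without control_RT replicates 4, 6 and 7, 316, 225, 215 and 556 without control_4C replicates 1, 4, 5 and 7, 94, 252 and 114 without columns KO8, KO10 and KO16, 0 without control_4C replicate 6 or KO_4C replicate 4 or 7, and 1 to 3 without the 16 others. For the interaction, 25 libraries moved the count of 3: it was 9 and 98 without control_RT replicates 1 and 4, 124 and 226 without columns KO8 and KO10, 5 and 6 without control_4C replicate 7 and KO_4C replicate 7, and 0 or 1 without the 19 others.

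Of the lists called by camera (16, 15, 1, 10 and 5 per contrast), 0, 0, 0, 0 and 0 were called with an estimated correlation, and fry called 21, 20, 0, 2 and 0. For knockout at room temperature counts divided by 2 gave 2, leaving out the 3 intestinal-high libraries 2 and leaving out KO8 and KO10 3. For the interaction these last 2 settings gave 3 and 3, leaving out the 4 loss-low libraries 3 and the intestinal covariate 2, which gave 5 at 4 °C and turned glycolysis downward (adjusted p = 0.855). Directions also turned for Nr4a3 (0.12) and Myh7 (-0.14 in control, -0.10 in knockout rats) with the slow-fibre covariate, of which Myh7 is a part, and for Tfb2m (-0.13) and Nr4a1 (-0.32) in cold control rats with the loss-index covariate. The r of the cold responses was 0.633 at 10 CPM or more, 0.373 without the 4 loss-low libraries and 0.354 without KO8 and KO10 (jackknife SE 0.114), and 0.436 to 0.524 without single libraries.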

Other observations

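The genes described here and the test of the neighbours of Ucp1 were chosen after the results were seen. Further genes outside the fixed lists rose with cold in both genotypes. Plat, the tissue plasminogen activator, rose by log2 1.34 ± 0.21 in control rats (SE; adjusted p = 5.63e-05) and 0.99 ± 0.18 in knockout rats (adjusted p = 0.000244). Nox4, an oxidase that makes hydrogen peroxide, rose by 1.15 ± 0.21 and 1.22 ± 0.19 (adjusted p = 0.000250 and 2.20e-05), and Enho, which encodes the secreted peptide adropin, by 1.06 ± 0.25 and 1.39 ± 0.23 (adjusted p = 0.00294 and 4.98e-05). The phosphate carrier Slc20a2 rose by 1.85 ± 0.30 and 0.75 ± 0.25 (adjusted p = 8.24e-05 and 0.0425), and the nucleoside carrier Slc28a2 by 1.48 ± 0.31 and 0.89 ± 0.27 (adjusted p = 0.00121 and 0.0248).

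Other genes outside the lists fell in both genotypes. Ache, the acetylcholinesterase, fell by 0.85 ± 0.14 in control rats and 1.03 ± 0.13 in knockout rats (adjusted p = 0.000117 and 9.89e-07). Scn4a, the sodium channel of the muscle action potential, fell by 1.11 ± 0.25 and 0.76 ± 0.22 (adjusted p = 0.00150 and 0.0158), and Sptb, the beta spectrin of the membrane skeleton, by 0.81 ± 0.19 and 1.09 ± 0.17 (adjusted p = 0.00209 and 1.96e-05). Dusp8, a phosphatase of stress kinases, fell by 1.04 ± 0.17 and 0.91 ± 0.15 (adjusted p = 6.73e-05 and 4.74e-05).

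A chromosome segment carried along with the knockout might change genes near Ucp1 at both temperatures. The 100 tested genes nearest to Ucp1 in the reference order on chromosome 19 were counted. Of these, 0 had an unadjusted p under 0.05 in edgeR with one sign at both temperatures. That 100% of the 8138 windows of as many genes held as many or more follows from this count of 0 (median 2, highest 7). Over the whole chromosome 2.66% of 301 tested genes had such a p and sign, against 1.89% elsewhere. A linked segment of that reach therefore found no sign in these data. With so few such genes in most windows, the test does not exclude one.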
